A study of Mus musculus with 7 samples.

How the data were processed

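RNA from the microdissected cardiac region of single mouse embryos at embryonic day 8.5 was profiled by bulk RNA sequencing, with 1 library per embryo. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, every RNA integrity number was above 9, and 20 ng of total RNA entered a kit that selects polyadenylated RNA and keeps strand. The labels also state 15 to 18 PCR cycles, an Illumina HiSeq2500, paired reads of 130 bases and a mean depth of 58M reads. HISAT2, featureCounts, Subread, DESeq2, edgeR and limma and the mouse build GRCm38 are named in the submitters' processing notes, without versions or roles. The annotation release and the settings of those tools are not given in the sources used here, so the strand setting of the counting is not known.

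The library values deposited by the authors are normalised signal values, and they turned out to be gene counts divided by 1 size factor per library: every value above 0 in every library was a whole multiple of that library's smallest step within a tolerance of 0.1, which is 100% of values. Whole reads were therefore recovered by dividing each value by its step. Recovered totals ran from 7155994 to 15122057 reads per library with a median of 12623459, and the normalised totals from 11226090 to 11714127. The authors' table of all genes also holds, per the file headers, group means of the normalised signal, the ratio of mutant to control means, a p-value and its Benjamini-Hochberg adjustment. A second table deposited by the authors holds selected genes with a ratio and p-values from DESeq2, edgeR and voom; its largest p-value was 0.0499 and its ratios were at least 1.20 or at most 0.833. The first line of the file headers gives a substage and a sex for each library: the 4 females are E8.5e and the 3 males E8.5f, so sex and substage cannot be separated. Whether the substage was staged per embryo is not given in the sources used here, and since it follows sex exactly it is used only as a label from the header. The table lists 48526 genes, of which 19544 had no read and 48144 were found by identifier in GENCODE M21 (GRCm38), which gave the coordinates and gene types printed here. For 14 genes the symbol had been turned into a date, and the GENCODE symbol was used.

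Groups were taken from the genotype in the labels: 4 control embryos (wild-type Hoxb1, 1 conditional and 1 intact Nodal allele) and 3 mutant embryos (1 Hoxb1 allele carrying the Cre recombinase, 1 conditional and 1 null Nodal allele), of mixed genetic background. Each embryo counts as 1 replicate. No label pairs embryos across the groups.

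The design chosen before the data were examined was edgeR's quasi-likelihood test on counts, or limma if no counts were present. Because the deposited values are normalised, genes were tested with limma 3.58.1 (trended empirical Bayes) on log2(normalised count + 1) in R 4.3.3, without covariates, and edgeR 4.0.16 on the recovered reads was run as an added alternative. Fold changes are on that log2 scale, which understates changes of genes with low counts. A gene entered the test with a normalised count of at least 10 in at least 3 libraries, which left 15599 genes; this filter replaced the planned edgeR filter and was set before the fit. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold. The Nodal gene, below the filter, was compared by an exact two-sided permutation test of log2(CPM + 1), where CPM is the usual scaling of recovered reads by the library total. Intervals and floors cover the spread between libraries or counting error only. A floor is 3 reads over the group's total.

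A set of 32 gene lists, fixed beforehand, were tested with limma's camera on the same log2 values with an inter-gene correlation preset at 0.01. The Benjamini-Hochberg adjustment ran over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. The fry test asks whether the genes of a list move one way on balance and does not compare the list with other genes. List names matched 714 symbols in the table and 1 did not match.

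The rule for named genes, also fixed beforehand, takes genes fixed by name, among them Nodal, Lefty1, Lefty2 and Hoxb1; then the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, a mean CPM of at least 1 in the higher group and groups that do not overlap, leaving out predicted genes; then up to 4 members with the smallest p of each list described. Some genes that the rule takes are not reported here. Which 16 lists to describe with named members was chosen after their values were seen, as were genes named from the authors' tables, from fits that leave out an embryo, and from the comparison of substages.

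Alternatives planned beforehand were library-size scaling, other filters, DESeq2 1.42.0, limma-voom, sex and embryo-number range as covariates, other thresholds and leaving out each embryo in turn. As the deposited factors are already of the DESeq2 kind, the planned swap between that kind and TMM was run as TMM. Chosen after seeing the data were edgeR on recovered reads, TMM, pseudocounts of 0.5 and 5, the mean level of the neural tube list as a covariate, and the female E8.5e embryos alone. The planned count tests use the recovered reads.

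The gene and list tests were tested on simulated counts for the comparison of mutants with controls, over 15599 genes with independent noise. The limma test recovered 28% of genes changed 1.5-fold, 68% of those changed 2-fold, 90% of those changed 4-fold and 96% of those changed 8-fold, and called 10 of 15350 unchanged genes. These shares come from a run with 50 genes changed at each fold, besides a raised list. Many true changes make the adjusted threshold easier to pass, and 2 genes passed in the real data. The shares may therefore overstate what the test could find there. Gstt1, at a log2 fold change of -2.66, did not pass in the real fit (limma adjusted p = 0.967). In the simulation a list raised 1.5-fold was recovered and 0 other lists were called. Smaller shifts of a list were not simulated. Since the simulated genes vary independently, this result cannot give the error rate of the list test in the real data. There the estimated inter-gene correlation ran from -0.014 for the apoptosis and p53 list to 0.849 for the sarcomere list. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. No raw reads were analysed here.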

Results

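The cardiac region of 7 mouse embryos was sequenced at the stage when the heart tube loops: 4 controls and 3 embryos in which Nodal, the secreted signal of left identity, was inactivated with a Cre recombinase expressed from the Hoxb1 locus. Hoxb1 is a homeobox gene of posterior heart precursors and other posterior tissues. The comparison asks which transcripts differ in the heart region when Nodal is missing. The mutants also carry Cre and an altered Hoxb1 allele, which the controls lack. By this design no difference below can be assigned to the loss of Nodal alone. Controls 1 to 4 yielded 13223545, 12693876, 10037739 and 7155994 recovered reads and mutants 1 to 3 11998513, 15122057 and 12623459. Xist, the X-inactivation transcript, stood at 949 to 1221 CPM in control females and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 or 1 read in control 1 and control 3, so the sex labels of these embryos matched their RNA, and they did in the other 5. Controls 1 and 3 and mutants 2 and 3 are female and of substage E8.5e, and controls 2 and 4 and mutant 1 are male and of substage E8.5f.

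Nodal itself (ENSMUSG00000037171, chromosome 10, 61417972 to 61425338, protein coding) was close to the detection limit in the controls and had no read in the mutants. Controls 1 to 4 had 9, 3, 6 and 0 Nodal reads, and mutants 1 to 3 had 0, 0 and 0. A count of 0 over the mutant reads allows a CPM of up to 0.0755 (3 reads over the group). The pooled control reads gave 0.418, which is 5.53-fold above that floor. This ratio leaves out the counting error of the control reads and the spread between embryos, so it is no lower bound on the difference. The difference in log2(CPM + 1) was -0.43, with a control mean of 0.43 ± 0.35 (SD, n = 4), and an exact two-sided permutation test gave p = 0.143, where the smallest p that 35 arrangements allow is 0.0286. Control 4 had 0 reads, as the mutants did, so Nodal checks the labels of the other 3 controls only. Lefty1 (ENSMUSG00000038793, chromosome 1, 180935022 to 180938400), the midline inhibitor of Nodal, had between 0 and 5 reads in every library and was not tested.

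Lefty2 (ENSMUSG00000066652, chromosome 1, 180893108 to 180899103, protein coding), a target and inhibitor of Nodal signalling, was nearly lost in the mutants. Its normalised read count was 425 ± 130.5 (SD, n = 4) in controls and 3.34 ± 1.70 (SD, n = 3) in mutants, 0.787% of the control mean, with 5, 2 and 4 reads in the mutants. The log2 fold change was -6.66 (SE 0.33, limma adjusted p = 0.000516). Atp10d (ENSMUSG00000046808, chromosome 5, 72203329 to 72298775), a phospholipid-transporting ATPase that GENCODE lists as a polymorphic pseudogene, fell from 128 ± 18.1 (SD, n = 4) to 37.6 ± 3.01 (SD, n = 3), a log2 fold change of -1.73 (SE 0.16, limma adjusted p = 0.0381). Every mutant lay below every control for both genes.

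These 2 genes were all that passed among 15599 tested, and 0 genes passed in the upward direction. At an unadjusted p under 0.05 there were 598 genes, 339 higher and 259 lower in mutants, where 780 would be expected by chance. The groups did not overlap for 5.78% of genes, against 5.71% by chance. On the recovered reads, edgeR called 1 gene, Lefty2, and DESeq2 called 8, all lower in mutants: Lefty2, Atp10d, Hoxb1, Gstt1, Gm9008, Vgll3, Gm8276 and Gm12191; limma-voom called 0, with 578 at an unadjusted p under 0.05. Without control 3 the count was 10 genes, and without any other single embryo it was 1, Lefty2.

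Hoxb1 also lay lower in every mutant than in any control, without passing the test. Hoxb1 (ENSMUSG00000018973, chromosome 11, 96365752 to 96368256), whose locus carries Cre in the mutants, had 635 ± 75.1 (SD, n = 4) in controls and 359 ± 42.7 (SD, n = 3) in mutants, 56.5% of the control mean, with a log2 fold change of -0.82 (SE 0.12, 95% interval -1.09 to -0.55, limma adjusted p = 0.581). DESeq2 on the recovered reads called Hoxb1, with an adjusted p of 1.55e-05.

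**Figure D1:**
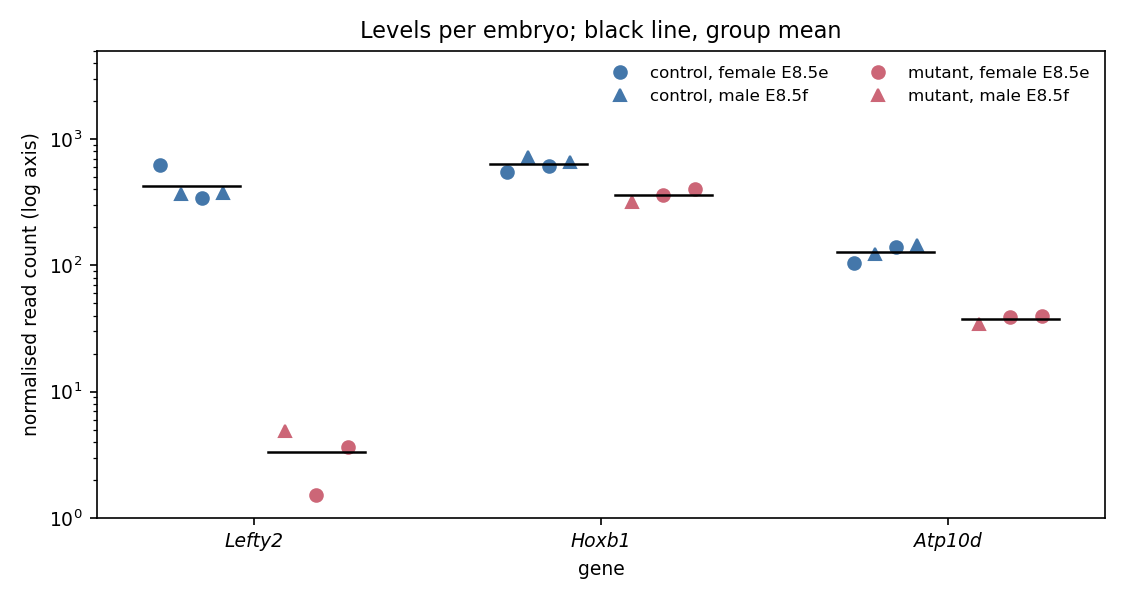
Normalised read count (log axis) of Lefty2, Hoxb1 and Atp10d in each of the 4 control and 3 mutant embryos; circles are female E8.5e and triangles male E8.5f embryos, and black lines are group means. Every mutant lies below every control for all 3 genes, with Lefty2 at 3.34 against 425 on average.

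The Nodal pathway list was lower in mutants (camera adjusted p = 0.0240; adjusted p = 0.638 with an estimated correlation). Of its 17 measured members 11 were lower and 6 higher, with a median log2 fold change of -0.05 and a mean of -0.55. Lefty2 was the 1 member that passed, both over all genes and adjusted over the list alone. Other members had values of -0.48 (Dand5, SE 0.24), a Nodal antagonist, and 0.18 (Smad3, SE 0.13), a signal transducer, neither of which passed. Without control 1, control 2, control 4 or mutant 3 the list did not pass (camera adjusted p = 0.0536, 0.0520, 0.0682 and 0.128), nor with DESeq2 (0.197) or the neural tube level as a covariate (0.159). Its median turned to 0.01 without control 1 and to 0.02 without mutant 3. It was -0.03, -0.15, -0.10 and -0.08 without control 2, control 3, mutant 1 and mutant 2. It was -0.11 with embryo number range as a covariate, -0.09 without the filter on low counts, -0.08 with edgeR and -0.01 in the female E8.5e embryos alone. By fry's mixed test, which takes changes either way, it was the 1 list that passed (adjusted p = 9.57e-05). Lefty2, at -6.66, is in the list and no list test without it is reported. Neither the camera nor the fry result can therefore be told from the change of that 1 gene.

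Transcripts of the contractile heart muscle were lower in mutants as groups, by amounts that depend on single embryos and with no single gene past the test. All 37 measured members of the sarcomere list were lower, with a median log2 fold change of -0.25 (camera adjusted p = 0.00104; adjusted p = 0.669 with an estimated correlation), among them Ttn, the giant elastic protein of the sarcomere (-0.74, SE 0.29), the slow skeletal troponin gene Tnnt1 (-0.75, SE 0.34), Neb (-0.29, SE 0.24) and the cardiac troponin gene Tnni3 (-0.55, SE 0.62). Of 21 calcium and conduction genes 17 were lower (median -0.24, camera adjusted p = 0.0242; adjusted p = 0.638 with an estimated correlation), including Pln, the brake on the calcium pump (-1.39, SE 0.43), and Camk2d (-0.40, SE 0.15), while the connexin gene Gjc1 stood at 0.10 (SE 0.05). Of 25 chamber and heart tube genes 20 were lower (median -0.18, camera adjusted p = 0.00866; adjusted p = 0.638 with an estimated correlation), including Shox2, a regulator of the sinus node (-0.72, SE 0.25), and the atrial regulators Nr2f2 (-0.22, SE 0.08) and Nr2f1 (-0.37, SE 0.18). In each of these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. The sarcomere call was lost without control 4 or mutant 2 (camera adjusted p = 0.190 and 0.516), the calcium call without control 1, control 2, control 4, mutant 2 or mutant 3 (0.0536, 0.101, 0.224, 0.217 and 0.128), and the chamber call without the same 5 embryos (0.0536, 0.101, 0.0966, 0.0688 and 0.111). The sarcomere median was -0.01 without mutant 2, -0.06 without control 4 and -0.14 without control 2, but -0.60 without control 3 and -0.57 without mutant 1 (camera adjusted p = 5.40e-13 and 3.91e-11). Without control 3 the calcium and chamber medians were -0.58 and -0.51 (camera adjusted p = 7.06e-06 and 1.57e-10). The calcium median was -0.14, -0.07, -0.46 and -0.07 without control 2, control 4, mutant 1 and mutant 2. The chamber median was -0.12, -0.07, -0.06 and -0.07 without control 1, control 2, control 4 and mutant 3, and -0.27 with edgeR. With sex as a covariate the sarcomere, calcium and chamber medians were -0.09, -0.11 and -0.10, and the 3 calls were kept (camera adjusted p = 0.0262, 0.0392 and 0.0432). In the female E8.5e embryos alone the sarcomere list kept its call (median -0.13, camera adjusted p = 0.0321), and the calcium list (median -0.01, 0.305) and the chamber list (median 0.03, 0.138) did not. The calcium call was also lost without the filter on low counts (0.0997).

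In both genotypes sarcomere levels were low in the embryos with high neural tube levels. The mean log2 level of the sarcomere list was 10.68, 10.79, 9.47 and 11.07 in controls 1 to 4 and 10.85, 9.72 and 10.11 in mutants 1 to 3, and the mean level of the neural tube list was 5.68, 4.23, 7.64 and 4.63 in controls and 5.22, 6.75 and 6.87 in mutants. The difference in mean sarcomere level was -0.28 with an SE of 0.50. With the neural tube level as a covariate, chosen after seeing the data, the median of the sarcomere list was 0.11, and neither the sarcomere list nor the calcium or chamber list passed (camera adjusted p = 0.237, 0.582 and 0.767).

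**Figure D2:**
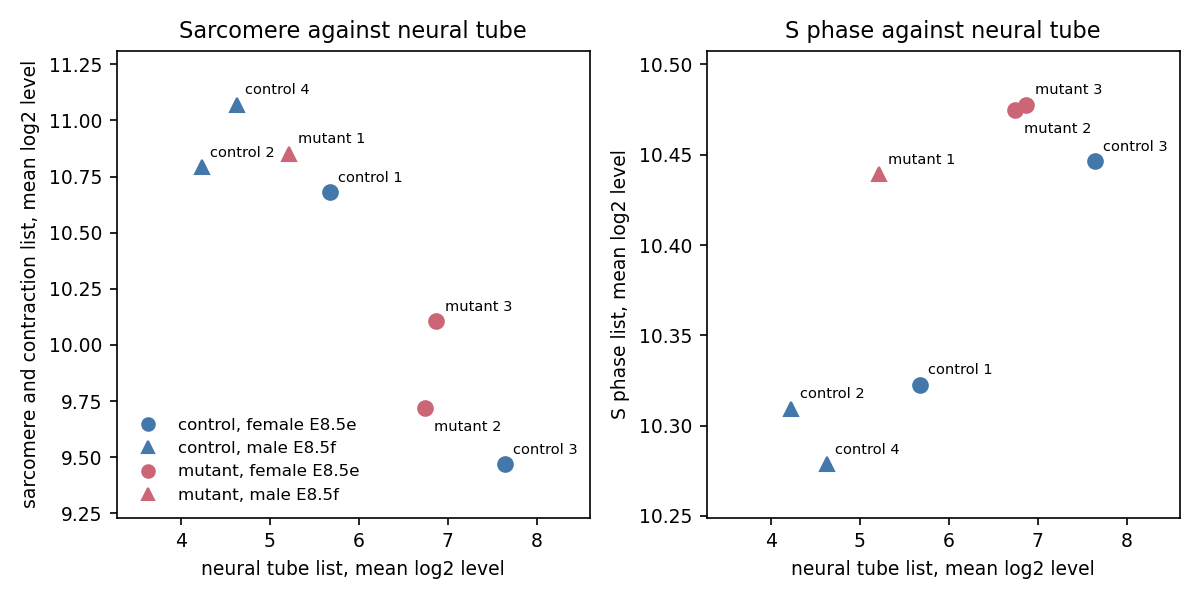
Mean log2 level of the sarcomere list (left) and of the S phase list (right) against the mean log2 level of the neural tube list, 1 point per embryo; colours mark genotype and shapes mark sex with substage. Control 3, mutant 2 and mutant 3 have the highest neural tube levels (7.64, 6.75 and 6.87) and the lowest sarcomere levels (9.47, 9.72 and 10.11).

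Extracellular matrix genes were lower in mutants: 44 of 50 measured members, with a median log2 fold change of -0.17 (camera adjusted p = 7.98e-06; adjusted p = 0.638 with an estimated correlation). The members with the smallest p encode fibrillar collagens and a small proteoglycan: Col5a2 (-0.50, SE 0.17), Col5a1 (-0.55, SE 0.22), Col1a1 (-0.33, SE 0.14) and Bgn (-0.21, SE 0.10). None passed singly over all genes or adjusted over the list alone. Per embryo, the mean log2 level of the list was 9.66, 9.87, 9.50 and 9.81 in controls 1 to 4. It was 9.48, 9.54 and 9.50 in mutants 1 to 3, so control 3 lay within the range of the mutants. Mutant 1, with a neural tube level of 5.22, had the lowest matrix level. The call was kept without each embryo in turn, although the median was -0.09 without control 2, -0.09 without control 4 and -0.10 without mutant 2, and -0.11 with sex as a covariate. It was lost in the female E8.5e embryos alone, 2 against 2 (median 0.01, camera adjusted p = 0.472). With the neural tube level as a covariate the median was -0.04 (camera adjusted p = 0.0198). Control 3 had the lowest Col5a1 among the controls, 2345 against 4267 or more, and without it Col5a1 (-0.78, SE 0.07, limma adjusted p = 0.0126) and the heart regulator Gata4 (-0.70, SE 0.08, limma adjusted p = 0.0361) were among the 10 genes called. Neither passed with all embryos. Without control 3 the neural tube levels were 5.68, 4.23 and 4.63 in controls and 5.22, 6.75 and 6.87 in mutants. That fit therefore cannot separate genotype from neural tissue in the sample.

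Genes of DNA replication were higher in mutants. All 30 measured S phase genes were higher, with a median log2 fold change of 0.14, and 29 of 30 with library-size or TMM scaling (camera adjusted p = 3.16e-10; adjusted p = 0.638 with an estimated correlation). The exonuclease gene Exo1 (0.23, SE 0.06), the replication licensing factor Cdc6 (0.22, SE 0.07), the cyclin gene Ccne1 (0.19, SE 0.06) and the replication clamp Pcna (0.20, SE 0.07) had the smallest p, and 0 members passed over all genes or adjusted over the list alone. The list's mean log2 level was 10.32, 10.31, 10.45 and 10.28 in controls 1 to 4 and 10.44, 10.47 and 10.48 in mutants 1 to 3, so control 3 lay above mutant 1. The call held in all 20 alternative fits that keep the preset correlation, with a median of 0.09 both with the neural tube level as a covariate and in the female E8.5e embryos alone. Mitotic genes were higher by less: 26 of 33 members of the G2 and M phase list, median 0.06 (camera adjusted p = 0.00248; adjusted p = 0.638 with an estimated correlation), among them Aurkb (0.15, SE 0.07), Bub1b (0.11, SE 0.06), Ccna2 (0.09, SE 0.05) and Birc5 (0.11, SE 0.06). That call was lost without control 4 or mutant 2 (camera adjusted p = 0.0966 and 0.0688), with the neural tube level as a covariate (0.0780), and in the female E8.5e embryos alone (0.101).

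Markers of tissues next to the heart differed between the groups, with large differences between embryos of 1 genotype. Of 22 neural tube genes 19 were higher in mutants (median 0.63, camera adjusted p = 0.0240; adjusted p = 0.665 with an estimated correlation), and of 17 paraxial mesoderm genes 14 (median 0.42, camera adjusted p = 0.00652; adjusted p = 0.638 with an estimated correlation). Pax6, a neural tube regulator, had normalised read counts of 65.7, 74.3, 989 and 113 in controls 1 to 4 and of 97.6, 764 and 1060.1 in mutants 1 to 3. Nkx6-1, a ventral neural tube marker, had at most 6.05 in controls 1, 2 and 4 and 266 in control 3, against 4.88, 172 and 301 in the mutants. Tcf15, a somite gene, had 16.4, 66.9, 312 and 19.6 in the controls and 112, 274 and 362 in the mutants. The hindbrain gene Egr2 went the other way, with 89.0, 2.75, 285 and 39.3 against 6.83, 6.09 and 9.05 (log2 fold change -2.43, SE 1.25). Surface ectoderm genes were higher in 13 of 18 cases (median 0.16, camera adjusted p = 0.0474; adjusted p = 0.638 with an estimated correlation), led by the epidermal regulator Trp63 (1.60, SE 0.47). None of these genes passed singly. The neural tube call was lost without control 2, control 4, mutant 2 or mutant 3 (camera adjusted p = 0.771, 0.131, 0.345 and 0.137) and the paraxial call without control 2, control 4 or mutant 3 (0.0954, 0.0536 and 0.128). The surface ectoderm call was lost without control 2, 3 or 4 or mutant 1 or 2 (0.0954, 0.446, 0.0966, 0.611 and 0.0656). The neural tube median was 1.06, 0.15, 1.06 and 0.38 without controls 1 to 4 in turn and 0.97, 0.21 and 0.31 without mutants 1 to 3. It was 0.26 with edgeR and 0.28 with sex as a covariate (camera adjusted p = 0.0363). The paraxial median was 0.81 without control 3 and 0.69 without mutant 1. The surface ectoderm median was 0.06, 0.02, 0.28 and 0.27 without control 3, mutant 1, mutant 2 and mutant 3. With DESeq2 the neural tube call (median 0.27, camera adjusted p = 0.0532) and the surface ectoderm call (0.0788) were lost. In the female E8.5e embryos alone all 3 calls were lost: neural tube (median 0.18, camera adjusted p = 0.603), paraxial mesoderm (median 0.34, 0.432) and surface ectoderm (median -0.02, 0.996). The paraxial call was also lost with the neural tube level as a covariate (median 0.21, 0.159), and the surface ectoderm call with embryo number range as a covariate (0.197) and with the filter on CPM (0.0517).

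Transcripts typical of the yolk sac were lower in the mutant group mostly through 1 embryo: 19 of 19 members, median -0.75 (camera adjusted p = 0.00104; adjusted p = 0.638 with an estimated correlation). The list's mean log2 level was 9.15, 8.53, 8.23 and 7.80 in controls 1 to 4 and 6.18, 9.11 and 8.11 in mutants 1 to 3, so mutant 1 stood apart, and without mutant 1 the median turned to 0.25 (camera adjusted p = 0.503), while without mutant 2 it was -1.53 and without control 1 -0.43. In the female E8.5e embryos alone it was -0.03 (camera adjusted p = 0.505), and with DESeq2 it was -0.19 (0.0839) and with edgeR -0.20. Rbp4, a retinol carrier, had 107 in mutant 1 and 608 to 1521 in the controls. The values of Apoa2 (-0.96, SE 0.65), S100g (-1.11, SE 0.77) and the retinoic acid hydroxylase gene Cyp26a1 (-0.48, SE 0.14) did not pass. Cyp26a1 did not follow mutant 1 alone: it had 280, 291 and 245 in mutants 1 to 3 and 295 or more in the controls.

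**Figure D3:**
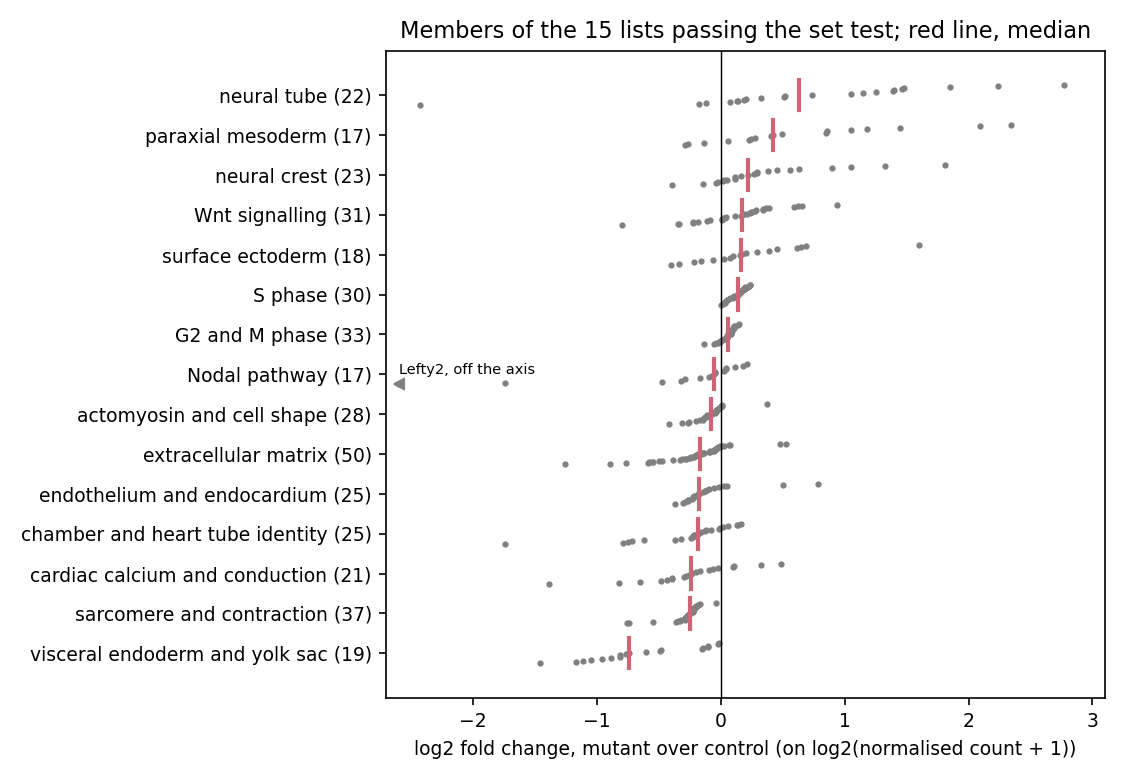
Log2 fold change, mutant over control, of each measured member (grey points) of the 15 lists that passed camera with the preset correlation; red lines are medians, the number of members is in brackets and Lefty2 (-6.66) lies off the axis. The medians run from -0.75 for the yolk sac list to 0.63 for the neural tube list.

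In all, 15 of 32 lists passed camera, 7 higher and 8 lower in mutants, and 0 passed with an estimated correlation or by the directional fry test. Besides those above, endothelial genes (21 of 25 lower, median -0.17, camera adjusted p = 0.00181) and actomyosin genes (23 of 28 lower, median -0.08, camera adjusted p = 0.00718) were lower, and Wnt signalling genes (23 of 31 higher, median 0.17, camera adjusted p = 0.0419) and neural crest genes (19 of 23 higher, median 0.22, camera adjusted p = 0.0300) were higher; each had an adjusted p of 0.638 with an estimated correlation. The endothelial call was lost without control 2 (0.133) and the actomyosin call without control 2, control 4 or mutant 3 (0.122, 0.0807 and 0.128). The Wnt call was lost without control 3 or 4 or mutant 1 or 2 (0.372, 0.198, 0.0674 and 0.0871), and the neural crest call without control 4 or mutant 1 or 2 (0.488, 0.173 and 0.0585). In the female E8.5e embryos alone all 4 calls were lost: endothelial (median -0.03, camera adjusted p = 0.609), actomyosin (median -0.03, 0.516), Wnt (median 0.10, 0.220) and neural crest (median -0.01, 0.516). With the neural tube level as a covariate the endothelial (median -0.05, 0.0780), actomyosin (median 0.01, 0.544) and neural crest (median 0.18, 0.133) calls were lost. With embryo number range as a covariate the Wnt and neural crest calls were lost (0.121 and 0.122), and with DESeq2 the Wnt call (0.0788). The endothelial median was -0.09 without control 2 and -0.29 without control 3. The actomyosin median was -0.04, -0.13 and -0.04 without control 2, control 3 and mutant 3. The Wnt median was 0.10 without control 4, 0.11 without mutant 1 and 0.10 with embryo number range as a covariate. The neural crest median was 0.11 without control 4, 0.15 without mutant 1 and 0.11 with DESeq2 or edgeR.

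The second heart field lists, which hold the precursors added to the heart tube, did not pass. In the anterior list 13 of 23 members were higher (median 0.01, camera adjusted p = 0.406), with Irx1 at 0.32 (SE 0.13), Fgf10, a growth factor of these precursors, at 0.21 (SE 0.09), and Foxc1 at 0.45 (SE 0.20). In the posterior list 14 of 25 were lower (median -0.08, camera adjusted p = 0.101), and in the Hox list 10 of 16 (median -0.25, camera adjusted p = 0.101), where Hoxb5 stood at -1.07 (SE 0.52) and Hoxb6 at -1.59 (SE 1.01). Hoxb6 had 2 reads in mutant 1, and its log2 fold change in the female E8.5e embryos alone was 0.02. The retinoic acid list had 12 of 19 members higher (median 0.12, camera adjusted p = 0.634), with Rxra at 0.19 (SE 0.08) and Rarg at 0.28 (SE 0.13). Cyp26a1, also a member, stood at -0.48 (SE 0.14). Hoxb1 was the 1 member of the posterior, Hox and retinoic acid lists that passed adjusted over the list alone (adjusted p = 0.00280, 0.00179 and 0.00212); over all genes it did not. The posterior list passed without control 1, control 3 or mutant 3 (camera adjusted p = 0.0170, 0.00250 and 0.0142), and the Hox list, as lower, without control 1, mutant 2 or mutant 3 (0.0300, 0.00339 and 0.00248). With edgeR the posterior list passed (0.0294), and without the filter on low counts the Hox list (0.0440). Without mutant 1 the median of the Hox list turned to 0.13, and in the female E8.5e embryos alone to 0.27 (camera adjusted p = 0.261 and 0.101).

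Signalling lists for BMP, FGF, Hedgehog and Notch did not pass (camera adjusted p = 0.659, 0.101, 0.101 and 0.406), nor did those for laterality at the node (0.397), glycolysis and hypoxia (0.153), primitive blood (0.153), endoderm (0.702), cranial and pharyngeal mesoderm (0.914), mitochondrially encoded transcripts (0.960), apoptosis and the p53 response (0.343), immediate early and heat shock genes (0.755), or X inactivation and Y-linked genes (0.450). Some of these passed in other fits. Without control 3 the BMP list was lower (median -0.21, camera adjusted p = 0.00250), the endoderm list lower (-0.22, 0.0407) and the Hedgehog list higher (0.29, 0.00463). Without mutant 1 the Hedgehog list was higher (0.26, 0.00168), and the lists for glycolysis (-0.09, 0.000522), primitive blood (-0.30, 0.0377) and cranial mesoderm (-0.23, 0.0394) were lower. The glycolysis list was also lower without control 1 (-0.07, 0.0101), without control 2 (-0.08, 0.00886) and in the female E8.5e embryos alone (-0.10, 0.00134), as was the cranial mesoderm list in those females (-0.23, 0.00557). The FGF list was higher without mutant 2 (0.14, 0.0222), without mutant 3 (0.12, 0.0244), with DESeq2 (0.09, 0.0406) and without the filter on low counts (0.08, 0.0135). The Hedgehog list was also higher without that filter (0.11, 0.0364) and with embryo number range as a covariate (0.15, 0.0459). The laterality list was lower without mutant 2 (-0.16, 0.0479). The heat shock list without mutant 3 (0.02, 0.0251) and the mitochondrial list without control 1 (0.16, 0.0436) were higher.

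Whether the genotype effect depends on sex, and with it on substage, was tested as an interaction with 3 residual degrees of freedom. With limma 0 genes passed and 390 had an unadjusted p under 0.05, while DESeq2 on the recovered reads called 20. The mutant group holds a single male, mutant 1.

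The authors' deposited table of all genes gives an adjusted p under 0.05 to 7 genes, Lefty2, Atp10d, Hoxb1, Gstt1, Gm9008, Vgll3 and Gm8276, all with a ratio below 1, and an unadjusted p under 0.05 to 601. The authors' deposited list of selected genes, 169 with a ratio above 1 and 312 below, was selected on unadjusted p-values of DESeq2, edgeR or voom, with 209 genes listed by all 3 tools and 195 by 1 tool only. Both genes called here, Lefty2 and Atp10d, are in it. Every gene on it was tested here and had the same sign, and 273 had an unadjusted p under 0.05 in the limma fit; both analyses use the same libraries, so this overlap is no independent evidence. Hoxb1 is on the list. Among the 32 lists, extracellular matrix genes took 8 places where 1.54 would be expected by chance (Fisher's exact test, adjusted p = 0.00212), all with a ratio below 1: Col1a1, Col1a2, Col3a1, Col5a1, Col5a2, Tnc, Postn and Fbln2. Immediate early and heat shock genes took 7 places where 0.833 would be expected (Fisher's exact test, adjusted p = 0.000422), 5 with a ratio above 1, among them Hspa1b, Dnajb1 and Hsph1, and 2 below, Egr2 among them. Hspa1b was high in mutants 1 and 2 only (208 and 222, against 29.9 in mutant 3). Fisher's test takes genes as independent, and the authors' genes were picked at unadjusted p-values in these libraries; camera with an estimated correlation gave the 2 lists adjusted p-values of 0.638 and 0.935.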

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

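The tests of Gstt1, Gm9008, Vgll3 and Gm8276, both tests of Hoxb1 and the sex covariate on the sarcomere list were chosen after the result was seen. So was the covariate for neural tube level, although its fits had not been run when their outcomes were written down.

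In 61 control groups checked, 1 control lay far from the other 3 for 9 genes, where chance gives about 1 in 20. Lefty2 in control 1 was 619, against 371 in the nearest control. Genes of 1 tissue can vary together, so the count of 9 cannot be set against the rate of 1 in 20. The other 8 were all in control 3. There the neural tube genes Pax6 (989), Nkx6-1 (266) and Hes5 (25.7), the somite genes Tcf15 (312) and Uncx (25.7) and the mesenchymal regulator Foxc1 (804) were high, where the nearest controls had 113, 6.05, 4.32, 66.9, 5.50 and 489. The collagen gene Col5a1 (2345) and the predicted gene Gm8276 (7.83) were low in control 3, where the nearest controls had 4267 and 77.7.

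The first pattern is that cardiac and matrix lists were lower, and neural and paraxial lists higher, in mutants. With the neural tube level as a covariate the sarcomere list's median moved from -0.25 to 0.11 and its call ended (mean level -0.28, SE 0.50, before and 0.06, SE 0.22, after), so different amounts of neural and somitic tissue in the dissections may account for the sarcomere difference; the matrix list kept its call, but its median fell from -0.17 to -0.037 while its mean level kept most of its value (-0.21, SE 0.10, before and -0.15, SE 0.07, after), so the values disagree and it cannot be told apart from such tissue. The S phase list kept its call with a median of 0.089 (mean level 0.12, SE 0.04, before and 0.09, SE 0.02, after), above 0.5 of its value without the covariate (0.0677). The neural tube level as measured thus did not take up the whole difference, though the median fell from 0.14. The margin is just over 1 SE, but that SE belongs to the mean level, and the 1 SE condition was added after this value was seen. The call also rests on the preset correlation (camera adjusted p = 0.638 with an estimated one, without the covariate), so neural tissue as a cause is not settled. Substage with sex, unequal between the groups, cannot be told apart for the sarcomere list, which kept its call with a median of -0.093. An effect of the genotype on heart muscle, matrix or proliferation, which the design names, stays open and was not separated from the tissue in the sample.

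The splits of the embryos bear on the same pattern. Of the 35 splits of the 7 embryos into 4 and 3, the real one included, 6 called at least the 2 genes of the real split, and the highest other count was 1060; 11 called at least its 15 lists, and the highest other count was 22. Chance is therefore not excluded for either count, which says nothing of the single gene Lefty2. The 1060 genes came from setting control 3, mutant 2 and mutant 3 against the rest, a structure of the samples that follows their neural tube levels and not the genotype, and the split of the 3 males from the 4 females called 13 genes and 21 lists.

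The second pattern is that 4 of the genes called in the authors' deposited table, Gstt1, Gm9008, Vgll3 and Gm8276, were lower in mutants. In 2 of them 1 control stood at the mutants' level with the other controls at least 5-fold above it: Gm9008 was 5.18 in control 1 and 72.7 or more in the others, and Gm8276 was 7.83 in control 3 and 77.7 or more in the others. Variants of the mixed background that segregate among the embryos may therefore set these levels, for Gm9008 and Gm8276 at least. Variants carried along with the engineered alleles were not resolved: of the genes called here 0 of 2 lay within 20 Mb of Nodal or Hoxb1, and of the genes with an unadjusted p under 0.05, Hoxb1 left out, the share was 5.53%, against 5.21% of the remaining genes (Fisher's exact p = 0.707), although Gstt1 lies 14.4 Mb from Nodal on chromosome 10. An effect of Nodal on these genes stays open. For Atp10d, which GENCODE lists as a polymorphic pseudogene, variants of the background were not tested either. Its normalised counts were 105 or more in the controls and 39.8 or less in the mutants, so no control stood at the mutants' level.

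The third pattern is Hoxb1 near 0.5 of the control level. The 95% interval of its log2 fold change, -1.09 to -0.55, includes -1, so 1 of the 2 Hoxb1 alleles carrying Cre may account for it. If less posterior tissue in the mutant dissections lowered the posterior list alike, its other 24 members would lie near Hoxb1. Their median was -0.048, with quartiles of -0.26 and 0.13, all above -0.41, which is 0.5 of the Hoxb1 value. That all members follow posterior tissue alike was not tested. In the Hox list 10 of 16 members were lower and 6 higher (median -0.25), with Hoxb5 at -1.07 (SE 0.52) and Hoxb6 at -1.59 (SE 1.01). These lower values depended on mutant 1. In the female E8.5e embryos alone Hoxb5 was at -0.21, Hoxb6 at 0.02 and the Hox median at 0.27, while Hoxb1 was at -0.61. Without mutant 1 the Hox median was 0.13 and Hoxb1 was at -0.73. The Hox list as a set thus did not fall with Hoxb1 in mutants 2 and 3, which argues against less posterior tissue there. For mutant 1 less posterior tissue is not excluded. An effect of Nodal on Hoxb1 cannot be separated from the allele, since every mutant carries both.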

How the results depend on the processing

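Chosen after seeing the data were edgeR on recovered reads, TMM, the other pseudocounts, the neural tube covariate and the females only. Among the named genes 0 values changed sign with a call, 14 lost a call and 8 gained one, and among the lists 74 calls were lost, 28 gained and 0 reversed over the alternatives. The count of genes differing by genotype, 2, became 8 with DESeq2 and 0 with limma-voom, and it was 1 with edgeR on the recovered reads, with sex, embryo number range or neural tube level as a covariate, and at an adjusted p under 0.01. It was 0 in the female E8.5e embryos only (2 against 2, so fewer samples), and from 1 to 10 when each embryo was left out, 10 without control replicate 3. The count stayed at 2 with library-size or TMM scaling, other filters and other pseudocounts. Lefty2 lost its call with limma-voom (adjusted p = 0.287) and in the females only (0.239), and its adjusted p otherwise ran up to 0.00757. Atp10d lost its call in 12 alternatives, with adjusted p-values from 0.0518 to 0.301 and a higher one in the females only.

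The count of lists, 15, became 5 with neural tube level as a covariate and 5 in the female E8.5e embryos only. It was 0 with the inter-gene correlation estimated per list and 0 with fry, and from 4 (without control replicate 4) to 17 (without control replicate 3) when each embryo was left out. The S phase list was the 1 list that passed in all 20 fits with the preset correlation; the matrix list passed in 19. The log2 difference of Nodal, -0.43 on the log2(CPM + 1) scale, became -5.28 with edgeR, -4.77 with DESeq2 and -3.11 with limma-voom, each with an unadjusted p under 0.05, on scales that depend on prior counts at this depth; it ran from -0.58 to -0.33 when each embryo was left out. The count of genes whose genotype effect differs by sex, 0, became 20 with DESeq2. The overlap with the authors' list, 2, became 8 with DESeq2 and 1 with edgeR. The causes of these changes were not tested, also where fewer samples enter. Nodal and Lefty1 had 9 reads or fewer in every library, which limits what can be said of them.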

Other observations

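The comparison of the 3 male E8.5f with the 4 female E8.5e embryos, with genotype in the fit, was chosen after the file headers showed the substage. Heart muscle transcripts stood higher in the male E8.5f embryos: 36 of 37 sarcomere genes (median log2 difference 0.93, camera adjusted p = 2.97e-22; adjusted p = 0.431 with an estimated correlation), 19 of 21 calcium and conduction genes (median 0.68) and 23 of 25 chamber genes (median 0.56). Female control 1 had a mean sarcomere level of 10.68, near the males (10.79, 11.07 and 10.85). The low levels were those of control 3, mutant 2 and mutant 3 (9.47, 9.72 and 10.11), which had the highest neural tube levels. Neural tube genes stood lower in the males, 20 of 22 (median -1.79, camera adjusted p = 7.04e-12; adjusted p = 0.431 with an estimated correlation), as did 17 of 19 yolk sac genes (median -1.36). Mutant 1 had by far the lowest mean yolk sac level, 6.18. The other males, controls 2 and 4, had 8.53 and 7.80, and the females ran from 8.11 to 9.15. In all, 21 lists passed camera, 12 higher and 9 lower, and the lowest adjusted p with an estimated correlation was 0.328. Of the 7 genes that passed limma's test, 6 are Xist or Y-linked, and the autosomal one is Msx3 on chromosome 7, a homeobox gene of the dorsal neural tube, with a mean normalised count of 61.4 in the females and 2.03 in the males (log2 difference -4.39, SE 0.43, adjusted p = 0.0250). On the first principal component, with 44.9% of the variance, control 3, mutant 2 and mutant 3 lay at 50.3, 22.3 and 32.0. These are the embryos with the highest neural tube levels. Control 1, also female, lay at -9.63, nearest to male mutant 1 (-22.1), and the 3 males ran from -22.1 to -42.3. The component therefore did not set sex or substage apart from neural tube level.

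For 3 heat shock genes, picked after their values were seen and with no test of the difference, mutants 1 and 2 stood above mutant 3 and every control. Hspa1b, an inducible chaperone gene whose reads cannot be fully told from those of its near-identical neighbour Hspa1a, had normalised counts of 32.0, 54.1, 22.4 and 22.9 in controls 1 to 4 and of 208, 222 and 29.9 in mutants 1 to 3. Dnajb1 had 879 or less in the controls and 1496, 1477 and 800 in the mutants, and Hsph1 had 4164 or less in the controls and 5896, 5991 and 3791 in the mutants. None passed the test over all genes. The mean log2 level of the whole list of immediate early and heat shock genes ran from 7.24 to 7.81 in mutants and from 7.26 to 7.80 in controls. The list passed only without mutant 3 among the fits that leave out an embryo (camera adjusted p = 0.0251). No explanation was tested.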
